A study of Homo sapiens with 4 samples.

How the data were processed

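The series holds 4 polyadenylated RNA libraries of the cell line PEO1-OR, 2 transduced with a control shRNA and 2 with an shRNA against ATF6. Per the labels' protocols, RNA was extracted with a column kit and made into directional mRNA libraries for paired-end sequencing. Per the submitters' processing notes the genome build was GRCh38. The aligner, the read counter, the gene annotation and the number of distinct hairpins are not given in the sources used here. The deposited values were log10 values, 1 per gene and library, for 35238 gene symbols, of which 12637 were at 0 in all 4 libraries. The table is named by the authors only as log CPM. The values themselves showed the scale: 10 raised to each value, minus 1, summed to 1000000 in every column, so each is log10(CPM + 1), where CPM is the count scaled to a library total of 1000000. Each column was a whole multiple of 1 step, from which 100% of values came back as whole reads (tolerance 0.001), with totals of 20611745 and 21539219 reads in the controls and 30820066 and 34739602 after knockdown. A single read was worth 0.0485 and 0.0464 CPM in the controls and 0.0324 and 0.0288 CPM after knockdown, so the knockdown libraries have the smaller counting error. Reads without molecular identifiers are not independent molecules.

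Columns were matched to samples by the sheet name, which sets control against ATF6 knockdown, and by their replicate numbers. The deposited column names give a hairpin code for the control columns. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 14.5 between controls and 69.1 between knockdown libraries, and all 4 were kept.

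Tests, gene lists, the rule for named genes and most alternatives were set before the data were examined, on the assumption of log2 CPM values. As foreseen there for decimal logs, the values were rescaled to log2(CPM + 1). A fold change on this scale understates the change of genes with low CPM. An alternative with a pseudocount of 1 CPM, also set then, coincides with the scale used, so a pseudocount of 0.5 CPM was added in its place. Genes with CPM above 1 in at least 2 of the 4 libraries were tested, 13569 in all, with limma 3.58.1 in R 4.3.3 (linear model, variance moderation with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Gene lists (43 fixed, of which 39 had at least 5 tested members) were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. None of the 15 lists past the camera threshold passed either of those. Over these 15 lists fry gave adjusted p from 0.108 to 0.573. Camera with an estimated correlation gave no list an unadjusted p below 0.0749. Its power with 2 libraries per arm was not measured, so a failure may reflect low power or the lack of a shift. Samples with the same replicate number are not stated to share a culture or a batch, so the comparison was unpaired.

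Named genes were ATF6, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2(CPM + 1) no lower than that of 2 CPM and both knockdown libraries on the same side of both controls, and up to 4 members with the smallest p of each list past the camera threshold and of 9 lists set in advance. Clone-based, antisense, LINC, LOC and pseudogene-like symbols counted in totals and were not named. Other genes named in the text were chosen after their values were seen.

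Alternatives were no filter, a stricter filter (mean at 2 CPM), quantile normalization, median centring, no variance trend, robust moderation, a replicate block, limma-voom on the recovered reads, larger folds, a smaller adjusted p, and leaving out each library in turn. Added after seeing the data were the smaller pseudocount, removal of a transcript length and GC trend from each library (loess, span 0.3), thinning of all libraries to the smallest total, and CPM without the 13 mitochondrially encoded mRNAs. Transcript length and GC content came from the longest basic transcript of each gene in GENCODE 29, a GRCh38 annotation that need not be the one the authors used; 27399 symbols matched directly, 12 by an older symbol and 7827 did not, and 95.8% of tested genes had a length. Coordinates are from the same annotation. The steps were tested on simulated counts for this comparison, over 13310 genes with a dispersion of 0.02 for every gene in both arms. On these counts limma recovered 85 of 99 genes changed by 1 and 99 of 99 changed by 2 on the log2 scale. Of 192 calls, 8 were unchanged genes. In the data, log2 differences between replicates had an SD of 0.268 in the controls and 0.375 in the knockdown arm. The simulated rates therefore check the steps and need not hold for these libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.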

Results

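Polyadenylated RNA was sequenced from PEO1-OR, a high-grade serous ovarian cancer cell line with acquired resistance to PARP inhibitors, drugs that block the repair enzyme poly(ADP-ribose) polymerase. Cells had been transduced with a lentivirus carrying either a control shRNA or an shRNA against ATF6, and transduced cells were selected with puromycin. Each arm had 2 libraries. ATF6 is a membrane protein of the endoplasmic reticulum (ER) that is cleaved under protein-folding stress, after which its released part switches on ER chaperone genes. The comparison asked which genes and pathways depended on ATF6 in these resistant cells. The control libraries held 20611745 and 21539219 assigned reads and the ATF6 shRNA libraries 30820066 and 34739602, and between 18542 and 19586 genes were detected per library. Across tested genes, Pearson's r of the log2 values was 0.992 between the 2 control libraries, 0.983 between the 2 ATF6 shRNA libraries and 0.955 to 0.969 across arms. Genes are not independent replicates, so these describe the libraries only.

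ATF6 mRNA was lower in both knockdown libraries than in both controls. The gene lies on chromosome 1 at positions 161766294 to 161964070 of GRCh38. It stood at 77.3 and 81.1 CPM (counts scaled to a library total of 1000000) in control replicates 1 and 2, from 1594 and 1746 reads. It stood at 12.6 and 19.3 CPM in knockdown replicates 1 and 2, from 389 and 669 reads. The group means were 79.2 ± 2.64 and 15.9 ± 4.69 CPM (SD, n = 2 each), a level 4.97-fold lower, or 79.9% below the control mean. On the log2(CPM + 1) scale ATF6 fell by 2.27 (SE 0.20, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00247). With 2 libraries per arm, an exact two-sided permutation test of 1 gene cannot go below 0.33. The ATF6 call was lost when control replicate 1 (adjusted p = 0.118) or control replicate 2 (adjusted p = 0.123) was left out of the limma fit. ATF6B, the paralog of ATF6, had a log2 difference of 0.49 and did not pass the threshold (limma, adjusted p = 0.065).

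Of 13569 genes tested, 1031 were higher and 1460 were lower after ATF6 knockdown (limma, Benjamini-Hochberg adjusted p under 0.05), and 373 and 253 of these differed by at least 1 on the log2 scale. The largest rise among the named genes was in IGFBP5, a secreted binding protein of insulin-like growth factors, with a log2 change of 7.17 (SE 0.88). Its knockdown libraries were far apart, at 158 and 1503 CPM, against 3.83 and 1.39 CPM in the controls. BGN, which encodes the extracellular matrix proteoglycan biglycan, went from 93.8 ± 14.2 to 1221 ± 167 CPM (SD, n = 2 each) (log2 change 3.69, SE 0.16). KRT13, a keratin of stratified epithelia, rose by 3.43, the acetyl-group receptor FIBCD1 by 3.23 and the helix-loop-helix transcription factor ATOH8 by 3.14 on the log2 scale. SMAD6, an inhibitory SMAD induced by bone morphogenetic protein (BMP) signaling, rose by 3.08, and ID1, an inhibitor of helix-loop-helix factors and a classical BMP target, rose by 2.91. The Wnt ligand WNT5A rose by 2.99, NKAIN4 by 2.98 and the secreted glutathione peroxidase GPX3 by 2.95. The size of several rises differed between the knockdown libraries, although each rise was seen with either library left out. Without knockdown replicate 2 the log2 change was 5.54 for IGFBP5, 2.76 for KRT13, 2.35 for WNT5A, 1.96 for NKAIN4 and 1.93 for GPX3. Without knockdown replicate 1 it was 8.79, 4.09, 3.63, 4.01 and 3.97. Adjusted p for these 10 genes lay between 0.000314 (BGN) and 0.0147 (NKAIN4) in limma, and those of IGFBP5, NKAIN4 and GPX3 no longer passed with robust variance moderation.

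Among the falls, ESM1, which encodes the secreted proteoglycan endocan, went from 125 ± 48.9 to 11.6 ± 3.53 CPM (SD, n = 2 each), 10.8-fold lower. MMP1, the interstitial collagenase, went from 16.2 ± 0.536 to 1.03 ± 0.238 CPM, 15.7-fold lower. EFR3B, a membrane adaptor of phosphatidylinositol 4-kinase, fell by 2.62 on the log2 scale, and the cell adhesion molecule CNTN1 fell by 2.15. In 1 family, 4 cancer-testis antigen genes fell, GAGE2E by 3.08, GAGE12F and GAGE12G by 2.93 each and GAGE1 by 2.56. GAGE12F and GAGE12G had identical values in every library (6.36 and 11.3 CPM in controls, 0.162 and 0.345 CPM after knockdown), and members of this near-identical family are uncertain as single genes, since how shared reads were counted is not given in the sources used here. RGPD6 fell by 3.97, the most of the named genes, but it is nearly identical to RGPD5, whose log2 difference was 0.31 without passing the threshold (adjusted p = 0.52), and its own control values were 36.7 and 10.4 CPM. Without control replicate 1 its log2 change was -3.11 and without control replicate 2 it was -4.83. Adjusted p for the 10 largest falls, ATF6 included, lay between 0.00108 (MMP1) and 0.00547 (RGPD6) in limma.

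The counts of changed genes depended on which libraries set the spread. A fit with 1 library left in an arm takes its spread from the other arm alone. Log2 differences between replicates had an SD over genes of 0.268 in the controls and 0.375 in the knockdown arm. The ATF6 fold moved little without control replicate 1 (-2.30) or control replicate 2 (-2.24). Without control replicate 1, limma called 0 genes in either direction, although 2447 had an unadjusted p under 0.05, and without control replicate 2 it called 1 higher and 1 lower. Without knockdown replicate 1 the counts were 1843 higher and 2448 lower. The split between directions depended on scaling: 41.4% of calls were rises on the deposited scale and 51.4% after quantile normalization (1088 higher, 1027 lower).

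ER chaperones and folding enzymes were lower after knockdown. The list was lower by camera (adjusted p = 0.000447). With an estimated correlation, camera gave adjusted p = 0.745, and fry gave adjusted p = 0.124. Of the 27 measured members, 14 fell, 1 rose and 12 did not pass; adjusted over the list alone, 16 fell and 1 rose. HSP90B1, the ER form of HSP90, went from 1034 ± 168 to 501 ± 9.20 CPM (SD, n = 2 each). HYOU1, a nucleotide exchange factor for the chaperone BiP, fell by 1.20 on the log2 scale, the BiP cochaperone DNAJB11 by 1.01 and the glycoprotein folding sensor UGGT1 by 0.96 (limma, adjusted p from 0.00547 to 0.00842). HSPA5, which encodes BiP itself, and its cochaperone DNAJC3 were singled out after their values were seen. HSPA5 stood at 1109 and 2111 CPM in the controls and at 618 and 516 CPM after knockdown, a fall of 2.84-fold (adjusted p = 0.0163), and DNAJC3 fell by 1.57 on the log2 scale (adjusted p = 0.00903). The peptidyl-prolyl isomerase FKBP2 rose by 0.56, and the abundant chaperone CALR had a log2 difference of -0.04 (adjusted p = 0.873).

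**Figure D1:**
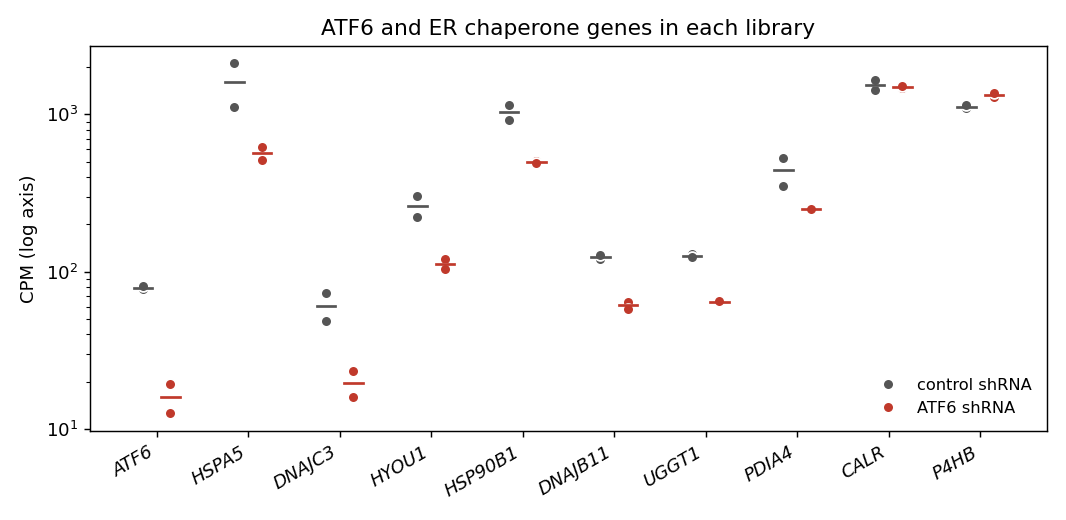
ATF6 and 9 ER chaperone or folding enzyme genes, in CPM on a log axis. Each point is 1 library (2 control shRNA, 2 ATF6 shRNA) and each bar the mean of the 2; ATF6 falls from 79.2 to 15.9 CPM and HSP90B1 from 1034 to 501, while CALR and P4HB did not pass the threshold.

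In the IRE1-XBP1 list, which holds genes of protein entry into the ER, 6 of 26 members fell and 1 rose (7 and 1 adjusted over the list alone). SSR3, a subunit of the translocon-associated protein complex, fell by 1.27, SEC63 by 0.87, the signal peptidase subunit SPCS3 by 0.88 and the mannosidase-like EDEM1 by 0.90 on the log2 scale (limma, adjusted p from 0.00677 to 0.0108). The list as a whole did not pass camera (adjusted p = 0.124). In ER-associated degradation, EDEM1 and FAF2 (log2 change -0.46) fell and the ubiquitin ligase RNF5 (0.60) rose among 22 members, with the same counts adjusted over the list alone, while TMEM129 had a difference of 0.66 that did not pass (adjusted p = 0.0629). The list did not pass camera (adjusted p = 0.124). Among 15 sensors and relatives of ATF6, ERN1, the gene of the sensor IRE1, fell by 0.80 and MBTPS2, which encodes the site-2 protease that cleaves ATF6, fell by 0.48 (limma, adjusted p = 0.0494); adjusted over the list alone, 1 fell and 0 rose. CREB3L2, a related membrane-bound transcription factor, had a log2 difference of -0.43 that did not pass (adjusted p = 0.0627). The list did not pass camera (adjusted p = 0.57).

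PERK-ATF4 targets were lower as a list, with a median log2 difference of -0.40 (camera, adjusted p = 0.026, and adjusted p = 0.745 with an estimated correlation). Of 34 members, 4 fell and 2 rose, the same counts as adjusted over the list alone. MTHFD2, a mitochondrial folate enzyme, fell by 1.20 and the cationic amino acid transporter SLC7A1 by 0.87 on the log2 scale, while the AP-1 repressor JDP2 rose by 1.10 and the stress protein NUPR1 by 1.12 (limma, adjusted p from 0.00659 to 0.0155). The camera call was lost without knockdown replicate 2 (median -0.16, adjusted p = 0.365), without control replicate 2 (median -0.23, adjusted p = 0.275) and with quantile normalization (adjusted p = 0.0586).

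Genes of DNA double-strand break repair were lower after knockdown. The 2 lists passed camera, homologous recombination with adjusted p = 0.00104 and end joining with adjusted p = 0.0212, and both had adjusted p = 0.745 with an estimated correlation. Of 39 homologous recombination genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone). XRCC2 fell by 1.01, the helicase BLM by 0.85, BRCA1 by 0.81 and the break-sensing kinase ATM by 0.76 on the log2 scale (limma, adjusted p from 0.0078 to 0.0167). Of 17 genes of non-homologous end joining, 5 fell and 0 rose, the same as adjusted over the list alone. PRKDC, the catalytic subunit of DNA-PK, went from 1032 ± 56.8 to 321 ± 8.61 CPM (SD, n = 2 each), 3.22-fold lower. RIF1, which acts against end resection, fell by 1.15, DNA ligase IV (LIG4) by 0.79 and the ubiquitin ligase RNF168 by 0.56 on the log2 scale (limma, adjusted p from 0.012 to 0.0242). The recombination genes that fell had long transcripts, with a median of 7788 nt against 2653 nt for the other members. With the length and GC trend removed, 4 recombination and 2 end joining genes fell, and ATM, LIG4, RIF1 and RNF168 no longer passed, at log2 differences of -0.31, -0.52, -0.66 and -0.34.

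Replication and cell cycle genes were also lower as lists, although most members did not pass the threshold. Camera gave adjusted p = 0.0212 for the fork list, 0.000547 for S phase and 0.00953 for G2 and mitosis, each with adjusted p = 0.745 with an estimated correlation. In the replication fork and checkpoint list, 6 of 24 members fell and 1 rose (8 and 2 adjusted over the list alone). The checkpoint kinase ATR fell by 0.72, its mediator CLSPN by 0.70, the fork protein TIMELESS by 0.62 and SLFN11, which blocks stressed forks, by 0.60 on the log2 scale (limma, adjusted p from 0.0136 to 0.0253). Of 33 S phase and E2F target genes, 10 fell and 0 rose (11 and 0 adjusted over the list alone). The epigenetic regulator UHRF1 fell by 0.82, the helicase component CDC45 by 0.77 and the helicase subunits MCM4 and MCM3 by 0.69 and 0.54 (limma, adjusted p from 0.0119 to 0.0244). Of 33 G2 and mitosis genes, 6 fell and 0 rose, the same as adjusted over the list alone. The other 27 did not pass, and 26 of the 33 were fitted lower and 7 higher. Among those that did not pass, PLK1, CDC20 and BIRC5 had log2 differences of 0.05, 0.04 and 0.01. TTK and BUB1, which also did not pass, had differences of -0.55 and -0.45. MKI67, the proliferation marker, went from 717 ± 49.0 to 349 ± 12.5 CPM (SD, n = 2 each), and the spindle and kinetochore genes CENPE, ASPM and CENPF fell by 1.20, 1.12 and 0.85. With the length and GC trend removed, 2 fork, 5 S phase and 4 mitotic genes fell. The 6 mitotic genes that fell had a median transcript length of 9460 nt, and the others 2797 nt. The fork call was lost with the length and GC trend removed (adjusted p = 0.0968), without control replicate 1 (adjusted p = 0.0639) and without knockdown replicate 2 (adjusted p = 0.0987), and the mitotic call without control replicate 1 (adjusted p = 0.115), without knockdown replicate 2 (adjusted p = 0.169) and with quantile normalization (adjusted p = 0.066).

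Lipid synthesis genes were lower as lists, and most so in knockdown replicate 2. Camera gave adjusted p = 0.00353 for fatty acid and 0.0392 for cholesterol synthesis, each with adjusted p = 0.745 with an estimated correlation. Of 18 fatty acid synthesis genes, 3 fell and 0 rose (5 and 0 adjusted over the list alone). Acetyl-CoA carboxylase (ACACA) fell by 1.18, fatty acid synthase (FASN) by 0.97 and ATP citrate lyase (ACLY) by 0.76 on the log2 scale (limma, adjusted p from 0.0117 to 0.0499), and GPAM had a difference of -0.52 that did not pass. FASN stood at 1630 and 1880 CPM in the controls and at 1232 and 649.8 CPM in knockdown replicates 1 and 2. Of 25 cholesterol synthesis genes, SREBF2, the transcription factor of the pathway, fell by 0.80 and the sterol reductase TM7SF2 rose by 1.01. Adjusted over the list alone, 0 fell and 1 rose. SREBF2 stood at 227 and 263 CPM in the controls and at 180 and 108 CPM in knockdown replicates 1 and 2. HMGCS1, the synthase upstream of HMG-CoA reductase, had a difference of -1.69 that did not pass (adjusted p = 0.0594), at 202 and 137 CPM in the controls and 98.9 and 25.8 CPM in knockdown replicates 1 and 2, and PMVK one of 0.45. Without knockdown replicate 2, neither list passed (adjusted p = 0.0987 and 0.908), and the cholesterol median went from -0.62 to -0.032. The cholesterol call was also lost without either control (adjusted p = 0.0671 without replicate 1 and 0.071 without replicate 2), without the low-value filter (0.0603) and with quantile normalization (0.055).

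NF-kappaB targets and cytokines were lower, with a median log2 difference of -0.71. Camera gave adjusted p = 0.000488 with all libraries, and the list had adjusted p = 0.745 with an estimated correlation. Of 24 measured members, 9 fell and 0 rose, the same as adjusted over the list alone. Complement component C3 went from 308 ± 60.8 to 82.5 ± 1.86 CPM (SD, n = 2 each), 3.74-fold lower, and manganese superoxide dismutase (SOD2) went from 423 ± 33.1 to 141 ± 3.33 CPM. The pentraxin PTX3 fell by 1.56 and NFKB1, which encodes the p50 subunit of NF-kappaB, by 0.99 on the log2 scale (limma, adjusted p from 0.00224 to 0.0106 over these 4 genes). TRAF1, CXCL8, BIRC3, IL6 and IL1A also fell, by 1.52, 1.47, 1.44, 1.29 and 1.12. The median was -0.27 without knockdown replicate 1 (camera, adjusted p = 0.0101).

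TGF-beta targets and mesenchymal genes were higher. Camera gave adjusted p = 0.000152 for the TGF-beta list and 0.00823 for the mesenchymal list, each with adjusted p = 0.745 with an estimated correlation. Of 22 TGF-beta list members, 8 rose and 0 fell (11 and 1 adjusted over the list alone). Besides ID1 and SMAD6, ID3 rose by 1.98 and ID2 by 1.16 on the log2 scale, as did CTGF by 2.06, TGFBI by 1.44, BAMBI by 0.77 and TGIF1 by 0.55. ID1, ID2, ID3, SMAD6 and BAMBI are known as targets of BMP signaling as well. Of 24 mesenchymal genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone). The matrix protein SPARC went from 803 ± 19.4 to 1748 ± 134 CPM (SD, n = 2 each), the collagen gene COL5A1 rose by 1.41 and fibrillin 1 (FBN1) by 1.07, while the fibronectin receptor subunit ITGA5 fell by 0.83. Fibronectin (FN1) was at 7111 and 18496 CPM in the knockdown libraries and 6366 and 7390 CPM in the controls, and did not pass (adjusted p = 0.236). The TGF-beta median, 0.60, was 0.30 without knockdown replicate 2 and 0.90 without knockdown replicate 1, and the mesenchymal median, 0.21, was 0.53 without control replicate 2 and 0.55 with the length and GC trend removed. The mesenchymal call was lost without the low-value filter (adjusted p = 0.0603), and COL5A1 and TGFBI no longer passed with robust variance moderation. The knockdown libraries of both genes were far apart. COL5A1 stood at 119 and 141 CPM in the controls and 241 and 496 CPM in knockdown replicates 1 and 2. TGFBI stood at 227 and 242 CPM in the controls and 440 and 923 CPM in knockdown replicates 1 and 2. Fibroblast markers, of which 4 were measured, held 2 that rose, COL1A1 (0.74) and THY1 (0.94), and 0 that fell (3 and 0 adjusted over the list alone).

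NRF2 targets were higher as a list, with 5 rises and 0 falls among 22 members, the same as adjusted over the list alone. The median log2 difference was 0.17, with 14 members fitted higher and 8 lower. Among the lower was the cystine transporter gene SLC7A11, at -1.32, which did not pass (limma, adjusted p = 0.0637). Camera gave adjusted p = 0.0456, with adjusted p = 0.745 with an estimated correlation. The iron storage gene FTH1 went from 2686 ± 87.6 to 8116 ± 615 CPM (SD, n = 2 each), 3.02-fold higher. FTL rose by 0.85, the quinone reductase NQO1 by 1.19 and the efflux pump ABCC3 by 2.60 on the log2 scale (limma, adjusted p from 0.00531 to 0.0117 over these 4 genes). The ABCC3 change was 1.81 without knockdown replicate 2 and 3.38 without knockdown replicate 1. The camera call of the NRF2 list was lost without the low-value filter (adjusted p = 0.0562), with the length and GC trend removed (0.126), without knockdown replicate 1 (0.118) and without control replicate 2 (0.109).

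Mitochondrially encoded mRNAs rose together: 12 of 13 rose and 0 fell, the same as adjusted over the list alone, with a median log2 change of 1.06. Camera gave adjusted p = 6.84e-09, with adjusted p = 0.745 with an estimated correlation, and fry gave adjusted p = 0.124. The preset correlation of 0.01 takes the 13 mRNAs as nearly independent, so the camera p is too small if they shift together. MT-ATP8, a subunit of ATP synthase, went from 436 ± 15.7 to 1203 ± 221 CPM (SD, n = 2 each). MT-ND6, MT-ND4L and MT-ND5, subunits of respiratory complex I, rose by 1.34, 1.23 and 1.16 on the log2 scale (limma, adjusted p from 0.00457 to 0.00909 over these 4 genes). The 13 mRNAs made up 2.10% and 2.67% of reads in the controls and 5.31% and 4.57% after knockdown. Cytosolic ribosomal protein genes held 4 rises and 0 falls among 37 (2 and 0 adjusted over the list alone), with RPLP1 up by 0.90, RPS15 by 0.69, RPL13 by 0.49 and RPS28 by 0.46. For this list camera gave adjusted p = 0.00113, with adjusted p = 0.745 with an estimated correlation. The ribosomal call was lost with the length and GC trend removed (adjusted p = 0.522) and without knockdown replicate 1 (adjusted p = 0.169).

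**Figure D2:**
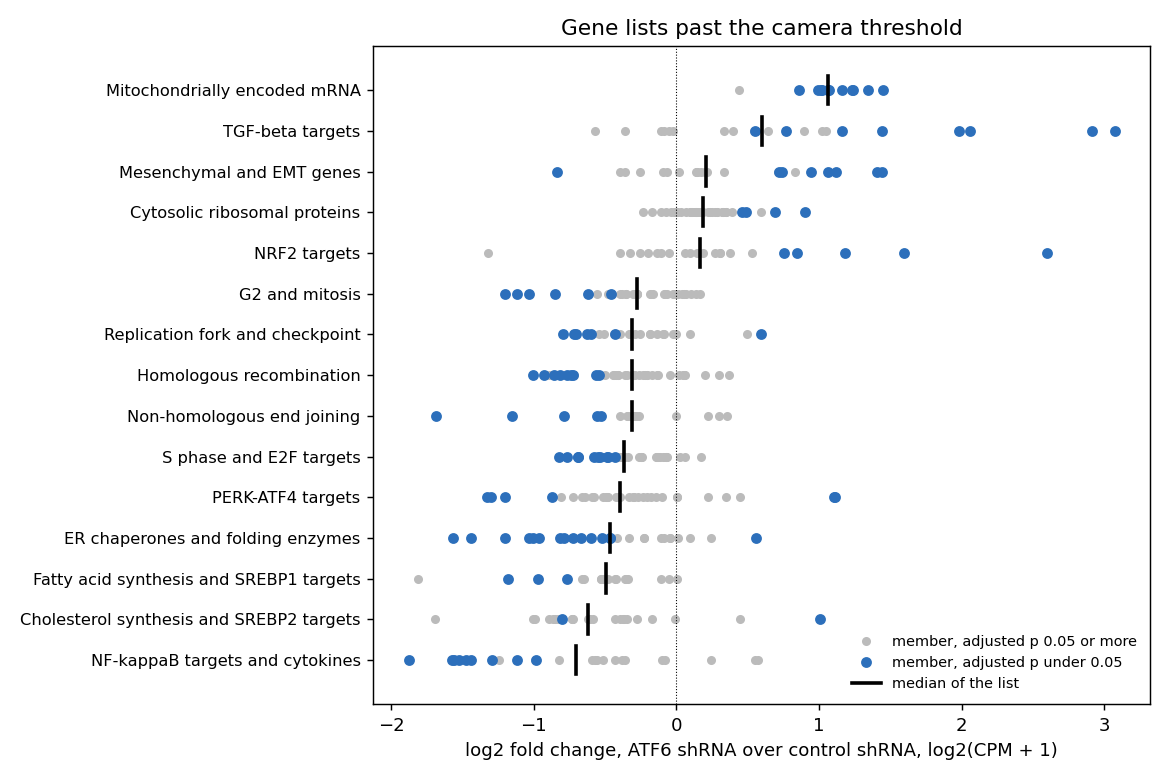
Log2 fold changes of the members of the 15 gene lists past the camera threshold, on the log2(CPM + 1) scale, ATF6 shRNA over control shRNA. Each point is 1 gene (blue, adjusted p under 0.05) and each black bar the median of a list, which lies below 0 for 10 lists and above 0 for 5.

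The Wnt list and the stress kinase list did not pass camera (adjusted p = 0.163 and 0.57). Of 17 Wnt genes, WNT5A and the R-spondin receptor LGR6 (log2 change 1.90) rose and cyclin D1 (CCND1, -0.58, adjusted p = 0.0492) fell; 4 rose and 1 fell adjusted over the list alone. The Wnt antagonist SFRP1 had a difference of 0.40 that did not pass (adjusted p = 0.0514). Of 27 p38 and JNK genes, the kinase MAP2K6 rose by 0.89, and the phosphatases DUSP4 and DUSP10 and the kinase MAP2K3 fell by 0.85, 0.81 and 0.72, with the same counts adjusted over the list alone. Among 26 immediate early and AP-1 genes, ETV4, ETV5, DUSP5, DUSP6 and SPRY4 fell by 1.17, 1.15, 1.38, 1.20 and 0.75, and JUND rose by 0.62 (6 fell and 1 rose adjusted over the list alone). EGR1 and FOS had differences of 2.30 and 1.61 that did not pass (adjusted p = 0.165 and 0.363), and the list did not pass camera (adjusted p = 0.375).

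The remaining lists did not pass camera or had too few tested members for it. Rises and falls were 0 and 2 of 17 for the Fanconi anemia pathway, 1 and 3 of 26 for PARP and base excision repair, 3 and 4 of 25 for p53 targets and 1 and 5 of 25 for apoptosis regulators. Adjusted over the list alone they were 0 and 2, 1 and 5, 3 and 4, and 1 and 5. They were 0 and 4 of 29 for hypoxia and glycolysis, 1 and 4 of 22 for heat shock proteins, 6 and 2 of 36 for interferon-stimulated genes and 1 and 0 of 17 for MHC class I presentation. Adjusted over the list alone they were 0 and 4, 1 and 7, 6 and 2, and 1 and 0. Epithelial genes had 3 and 3 of 30, Hippo-YAP targets 2 and 2 of 24, Mullerian markers 4 and 1 of 15 and drug transporters 1 and 5 of 18. Adjusted over the list alone they were 3 and 4, 2 and 2, 7 and 2, and 1 and 5. ER-to-Golgi transport had 3 and 5 of 35, autophagy and lysosome 2 and 2 of 29 and nuclear genes of oxidative phosphorylation 4 and 0 of 31, or 3 and 5, 2 and 2, and 3 and 0 adjusted over the list alone. No member passed among 5 replication-dependent histone genes or 15 housekeeping genes, also when adjusted over the list alone. Of other cell type markers, the endothelial gene ROBO4 fell by 1.51 (1 of 5), the myeloid genes CD14 and CD68 rose by 0.86 and 0.59 and ITGAM fell by 0.99 (3 of 4 leukocyte genes), and the neuronal gene MAP2 rose by 1.34 (1 of 4). Adjusted over the list alone, falls were 1 for endothelial and 1 for leukocyte markers, and rises 2 for leukocyte and 3 for neuronal markers. No globin or adipocyte gene passed the low-value filter.

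Direction followed transcript length across genes. Genes that rose had a median transcript length of 2243 nt, genes that fell 5638 nt and genes that did not pass 3314 nt. Of transcripts up to 1000 nt, 22.7% rose and 1.99% fell, and of those over 8000 nt, 3.20% rose and 32.9% fell. Across 12997 genes, Spearman's rho of the log2 fold change was -0.364 with transcript length and 0.399 with GC content; genes are not independent replicates, so no p is given. With both trends removed from each library, 723 genes were higher and 743 lower, of which 1210 were among the 2491 called on the deposited scale, and ATF6 fell by 1.92 (limma, adjusted p = 0.0076). Of the named genes, ACLY, ATM, ATR, CCND1, CENPF, CLSPN, DUSP10, ERN1, FAF2, FASN, LIG4, MBTPS2, RIF1, RNF168, RNF5, RPL13, RPS15, RPS28, SLFN11 and SREBF2 lost their calls. Some of these kept folds of about the same size, with FASN going from -0.97 to -1.03, SREBF2 from -0.80 to -0.78, RPL13 from 0.49 to 0.50, ACLY from -0.76 to -0.70 and DUSP10 from -0.81 to -0.73. Others shrank, with ATM going from -0.76 to -0.31 and RPS15 from 0.69 to 0.11.

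**Figure D3:**
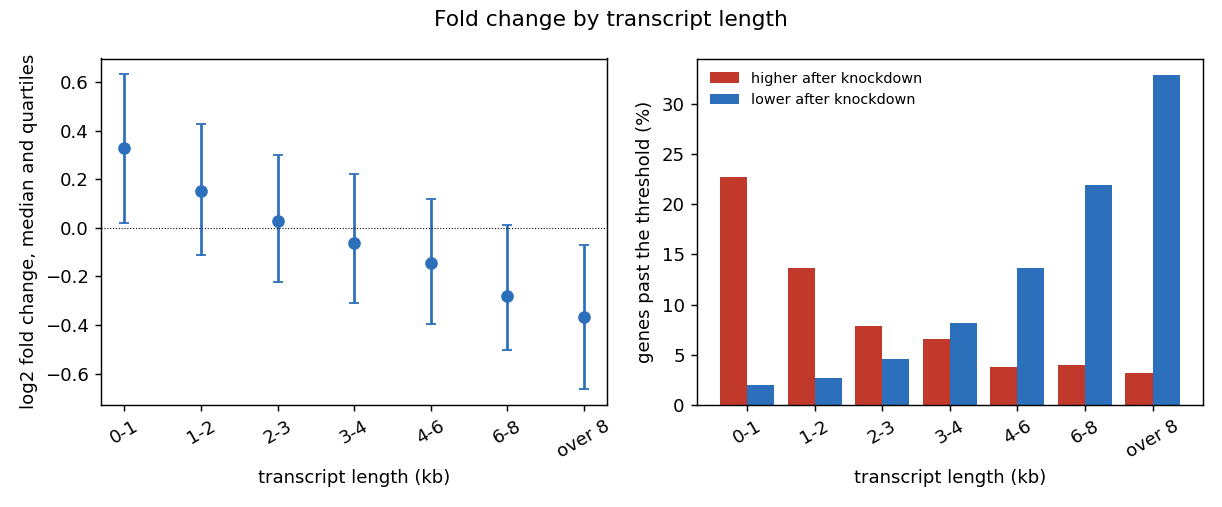
Log2 fold change of genes grouped by transcript length in kb, as medians with quartiles, and the percentage of each group that was higher or lower past the limma threshold. The share that fell grows from 1.99% up to 1000 nt to 32.9% over 8000 nt.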

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

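The pseudocount of 0.5 CPM, the length and GC correction, thinning and the scale without mitochondrial mRNAs were chosen after seeing the data. ATF6 was lower under every alternative, from -2.56 to -1.98 with 1 library left out, and lost its limma call without the filter (-2.27, adjusted p = 0.164) and without either control; its adjusted p elsewhere was at most 0.013. The counts of genes higher after ATF6 knockdown and genes lower after ATF6 knockdown, 1031 and 1460, became 11 and 98 with no filter, where 12637 all-zero genes enter the fit. They became 857 and 898 with no variance trend, 723 and 743 with the length and GC trend removed, 373 and 253 at a log2 change of at least 1, and 178 and 239 at an adjusted p under 0.01. With 1 library left out the counts ran from 0 to 1843 higher and from 0 to 2448 lower; the arm left with 1 library is then assumed to vary like the other. Without control replicate 1 limma called 0 and 0 (2447 with an unadjusted p under 0.05) and without control replicate 2 it called 1 and 1 (2977). Except for the stricter thresholds, the cause was not tested. Quantile normalization, median centring, robust moderation, voom on recovered reads, the smaller pseudocount, the stricter filter, thinning and removal of mitochondrial mRNAs kept both counts within 1.5 times. Of the lists past camera, 15, 0 passed with an estimated correlation and 0 with fry. With an estimated correlation the smallest unadjusted camera p of any list was 0.0749, and the power of that test with 2 libraries per arm was not measured. The cholesterol list turned to the upward camera direction without knockdown replicate 2, at a median of -0.032 (adjusted p = 0.908); its median ran from -1.17 without knockdown replicate 1 to -0.032. Of 88 named results past the threshold, 20 lost their call with the length and GC trend removed (some at folds of the same size, such as FASN at -1.03 and RPL13 at 0.50), 8 with quantile normalization, 6 with voom, and 88 without the filter or without control replicate 1; none changed sign. With the replicate block the counts were 1770 and 2495; same-numbered libraries share only a number, and their deviations from the group means had a correlation of 0.225 across genes. Depth limits low genes most: 3 reads are 0.146 CPM in the shallowest library.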

Other observations

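The tests on GC content and on mitochondrial pseudogenes were chosen only after the result was seen. Genes in this paragraph were picked after their values were seen and were not tested as a group. Several keratin genes were higher after ATF6 knockdown, and others were not. Besides KRT13, KRT14 rose by 2.69, KRT15 by 1.89, KRT16 by 1.46 and KRT5 by 1.10 on the log2 scale, as did IVL, a component of the cornified envelope, by 1.90 (limma, adjusted p from 0.00317 to 0.0179). KRT18, a keratin of simple epithelia, had a difference of -0.18 (adjusted p = 0.463), KRT34 fell by 2.02 and the desmosomal gene DSP by 1.16, and the junction genes JUP and PKP3 had differences of 0.12 and 0.02 that did not pass. GATA3, a transcription factor of squamous and luminal cells, went from 14.5 ± 0.0865 to 80.5 ± 41.4 CPM (SD, n = 2 each). The retinoic acid receptor gene RARB rose by 1.74, and PPARG fell by 1.40. ID4 rose by 1.07, so all 4 ID genes were higher, while the BMP ligand gene BMP4 had a difference of 0.01 (adjusted p = 0.988). The growth factor genes FGF2 and FGF5 fell, FGF2 from 208 ± 18.7 to 74.5 ± 15.7 CPM and FGF5 from 57.6 ± 3.84 to 17.0 ± 0.255 CPM (SD, n = 2 each). The glycolytic enzyme HK2 fell by 1.59 and the epithelial factor EHF by 1.96, and TNFSF10, the gene of the death ligand TRAIL, rose by 2.27 on the log2 scale.

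Long transcripts were lower after knockdown. Thinning all libraries to the smallest left Spearman's rho of fold change and length at -0.363. Thinning keeps the expected CPM of each gene, so it could hardly move rho. It does not decide whether deeper sequencing of the knockdown libraries played a part. Library preparation or RNA quality that varies from library to library stays open and cannot be told apart from the knockdown for length: the difference between the 2 knockdown libraries had a rho of 0.114 with length and that between the 2 control libraries one of -0.105, signs that depend only on the order of subtraction, against -0.364 between arms. For GC-rich transcripts, which were higher after knockdown, the 2 control libraries differed with a rho of 0.347 against 0.399 between arms, so variation between libraries alone may give a trend of that size. An effect of the knockdown on long transcripts was not separately tested.

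For the repair and cell cycle lists, which were lower after knockdown, a trend with transcript length and GC content is argued against as the whole cause, because 4 of the 5 lists kept their camera call with the trend removed, although all 5 had adjusted p = 0.745 with an estimated correlation on the deposited scale and none passed fry. At least part of the list differences may come from the trend. The members that fell went from 9 to 4 for homologous recombination and 5 to 2 for end joining. They went from 6 to 2 for the fork list, 10 to 5 for S phase and 6 to 4 for mitosis. The median log2 difference went from -0.31 to -0.21 for homologous recombination, from -0.31 to -0.15 for end joining, from -0.36 to -0.30 for S phase and from -0.28 to -0.15 for mitosis (also -0.13 without control replicate 1 and -0.15 without knockdown replicate 2). The fork list went from -0.31 to -0.12 and lost its camera call (adjusted p = 0.0968), and the SD of fold changes over its members went from 0.35 to 0.27. An effect of the knockdown itself stays open and was not separately tested.

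Mitochondrially encoded mRNAs were higher after knockdown. Pseudogene rows gained 2.13% of what the mRNAs gained in CPM, which does not decide whether reads shared with nuclear mitochondrial pseudogenes play a part. Those rows held 218 and 255 CPM in the controls and 878 and 686 CPM after knockdown. The mRNAs held 21036 and 26745 CPM in the controls and 53148 and 45714 CPM after knockdown. Shared reads counted only to the mRNAs would not show in the pseudogene rows. A trend with transcript length and GC content is argued against, since the median log2 change was 0.998 with the trend removed. RNA handling that differed between the arms was not tested and may contribute, as the knockdown and the library preparation cannot be separated with 2 libraries per arm.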
